A study of Caenorhabditis elegans with 2 samples.

How the data were processed

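Chromatin immunoprecipitation and sequencing was done on late embryos of Caenorhabditis elegans that carried a transgene for SYD-9 with a GFP and FLAG tag at its C-terminal end. The hermaphrodite worms bore an unc-119 mutation and were collected 4 h after synchronisation by egg bleaching. DNA was precipitated with an antibody against GFP, and there were 2 biological replicates in 1 group. The series holds no second group, stage or strain, so every comparison was made within this set of regions or against the genome.

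The authors deposited region lists for each replicate, for the pooled alignments and for the regions kept by an irreproducible discovery rate (IDR) threshold, in a set labelled optimal. Each list came in builds ce10 and ce11. The signal value of a region, in the deposited lists, is the authors' peak caller score relative to a control, on a scale that was not stated. A further deposited column holds -log10 of a q-value by the layout of the format and was used to describe regions, not to rank them. The peak caller, its version and the IDR threshold were not given in the sources used here. The lists hold no read counts, so the depth per replicate is unknown and no interval that needs depth was computed. The replicate lists reach far below the IDR set, since they were made as input for the IDR step and include background regions, and scores of different lists need not share a scale. In ce11 the IDR set was the 941 highest-scoring regions of the pooled list, each with the same summit and signal value. Signal tracks and alignments were not used here.

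Coordinates are in ce11, and the annotation was Ensembl release 115 with RefSeq symbols paired to genes by their WormBase identifiers. Annotated 5' ends stand for transcription start sites, because most worm transcripts are trans-spliced. A gene was called bound when a summit lay within 500 bp of one of its 5' ends. Small RNA genes were all annotated tRNA, snoRNA, snRNA, miRNA and rRNA genes, with a summit within 200 bp. Positions within genes were assigned by the summit base in the order coding exon, 5' UTR, 3' UTR, intron and intergenic, from protein-coding genes.

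Shares of summits near annotated features were compared with 1000 circular shifts of the summits along each chromosome, with one-sided permutation tests. The replicates were compared through the 941 highest-scoring regions of each list, with summits within 200 bp counted as shared, and through Spearman's rho of their signal values across IDR regions, with a 95% interval from 1000 bootstrap resamples of regions. Regions are not replicates, so rho carries no p. Shares by chromosome were compared with the share of protein-coding genes by two-sided exact binomial tests, and intervals of shares are exact 95% Clopper-Pearson intervals that cover counting error only. Some regions overlap, such as those upstream of rps-24, and each was counted separately in every exact binomial test and in Fisher's tests of regions. The p-values of those tests can therefore be too small and the intervals too narrow. Divergent promoters were compared with 1000 draws of positions within 500 bp of gene 5' ends by a two-sided permutation test, and signal values with a two-sided permutation test of 100000 resamples. Bound genes were tested against all 19973 nuclear protein-coding genes with Fisher's exact test, two-sided, for 18 lists, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Each 6-mer, merged with its reverse complement, was tested by a two-sided exact binomial test of regions that held it only within 50 bp of the summit against regions that held it only in a window of equal length 200 to 300 bp away. Benjamini-Hochberg adjustment ran over all 2080 6-mers, with a threshold of 0.01.

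The tests, lists, main settings and first set of alternatives were fixed before the data were examined. The tests of positions within genes and of tRNA isotypes were not part of that design. The 18 lists cover synaptic vesicle and active zone genes, neuronal transcription factors, axon guidance, body wall muscle, epidermis, intestine, pharynx, germline, ribosomal proteins, core histones, splicing, heat shock and folding, the mitochondrial respiratory chain, patterning factors, chromatin regulators, the cell cycle, nuclear hormone receptors and chemosensory receptors. Named genes follow a rule: the 25 IDR regions with the highest signal value, up to 4 bound members of each list by signal value, syd-9 as the tagged gene, unc-119 as the strain's marker, and the 3 enriched 6-mers with the lowest p after merging overlapping words. Other regions and small RNA genes that are named were chosen after their values were seen. List members were first matched by Ensembl symbol. After those results were seen, matching was changed to WormBase identifiers, because several histone genes shared a symbol, and the earlier matching was kept as an alternative. In all, 2 list members, hrp-1 and elt-5, matched no gene. The design assumed that flanks and summits have nearly the same base composition, which proved false: the flank windows had 37.5% GC and the summit windows 50.9%, so 6-mer counts against dinucleotide shuffles of the summit windows stand beside the others.

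The alternatives were leaving out each replicate, a stricter set of the 470 highest-scoring regions, other distances and overlap rules, the ce10 lists, expected shares from length, backgrounds of weaker candidate regions, circular shifts for the lists, shuffles and 8-mers. Those chosen after the results were seen were nuclear chromosomes only, the omission of summits at small RNA genes, symbol matching, and divergent promoter draws matched to the summits' sides and distances. A test of reads shared between gene copies was first run over all small RNA genes together (24.6-fold at 576 genes with unique surroundings) and was split by class after that result was seen. Surroundings took in the gene itself and a short flank on each side, and nearly all of their short words had to occur once in the genome. A gene whose own sequence is repeated could therefore fail even with unique flanks. The code was tested on simulated data. Random summits passed the 5' end test in 13 of 200 sets and the small RNA test in 6 of 200 sets, and planted enrichments were recovered. The number of random sets was raised after an early run with fewer. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with random seed 1.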

Results

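The data are maps of the regions precipitated with SYD-9-GFP in late embryos of Caenorhabditis elegans. SYD-9 is a zinc finger protein known for its role in synaptic vesicle organisation, and it was precipitated through a GFP tag in 2 biological replicates of 1 group. The ce11 lists held 10468 regions in replicate 1, 20425 in replicate 2 and 13472 in the pooled data. The IDR threshold kept 941 regions with a median width of 460 bp, of which 923 lay on nuclear chromosomes and 18 on mitochondrial DNA. The region score is the authors' and had a median of 131 over the IDR regions, with a range of 95.2 to 932.3. Depth per replicate is unknown.

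Both replicates marked largely the same places. Of the 941 highest-scoring regions of replicate 1, 656 (69.7%) had the summit of one of replicate 2's 941 highest-scoring regions within 200 bp, against 1.15% with shifted summits. The permutation test gave a one-sided p of 0.001, the smallest that 1000 shifts can give. Across the 935 IDR regions with a region of each replicate within 200 bp of the summit, Spearman's rho of the signal values was 0.563 (95% bootstrap interval 0.507 to 0.615), and regions are not independent replicates. The region upstream of K12H4.5, the highest in the pooled data, scored 443 in replicate 1 and 490 in replicate 2.

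**Figure D1:**
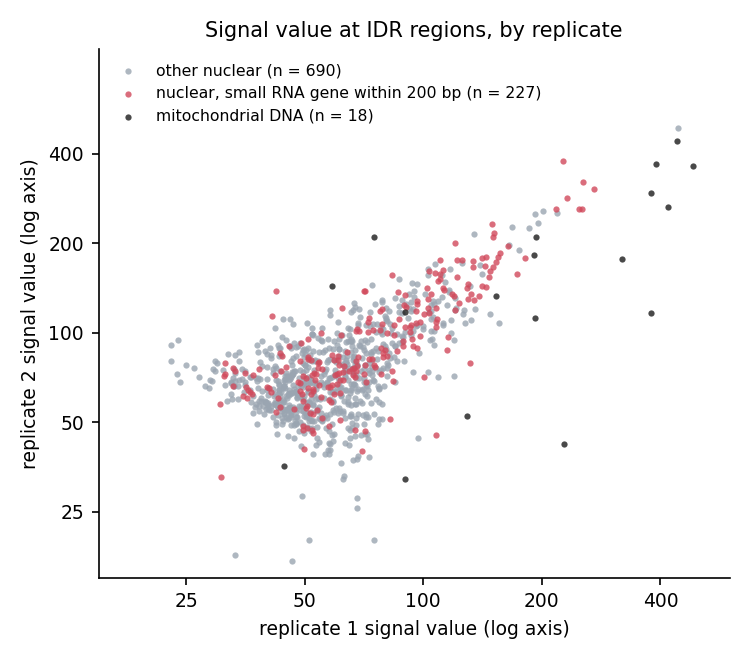
Signal value of IDR regions in replicate 1 (x, log axis) and replicate 2 (y, log axis), for the 935 regions found in both. Each point is a region, red at nuclear small RNA genes and black on mitochondrial DNA, and rho over all points is 0.563.

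The strongest regions fell at snoRNA genes, at a tRNA gene, upstream of a few protein-coding genes and on mitochondrial DNA. Of the 25 regions with the highest signal value, 8 were mitochondrial and 17 nuclear, and 9 of the nuclear summits lay within 200 bp of a small RNA gene. The highest score, 932.3, belonged to an intergenic region on III (8043778 to 8044164) with its summit 525 bp upstream of K12H4.5. An intron of frm-7, a FERM domain gene, held the strongest snoRNA region on V (12303467 to 12303758, score 609), whose summit lay in the snoRNA gene C51F7.4 with C51F7.3 beside it. Regions at the snoRNA genes ZK265.10 on I, T06C12.16 on V, W03C9.9 on II, ZK994.7 on V (in an intron of pxn-1, a peroxidasin gene) and Y43F8C.22 on V followed, with scores of 585, 577, 513, 510 and 479. The highest nuclear tRNA region lay on X (13665406 to 13665694, score 526), with its summit 10 bp into the tRNA-Leu gene C04A11.t1. The microRNA gene mir-51 on IV and the snoRNA gene T02E1.9 on I had regions that scored 377 and 364.

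Protein-coding genes with top regions included rpl-3, atx-2, idhg-1 and tasp-1, all on III with intergenic summits. The summit at rpl-3, which encodes a ribosomal protein, lay 282 bp upstream at 3867572 (score 478, with 219 in replicate 1 and 254 in replicate 2). Those at atx-2 (an ataxin-2 homologue), idhg-1 (an isocitrate dehydrogenase subunit) and tasp-1 (a threonine aspartase homologue) lay 46, 56 and 43 bp upstream, with scores of 455, 410 and 393. A pair of adjacent regions on IV had summits 500 and 700 bp upstream of eel-1, a HECT ubiquitin ligase gene, with scores of 446 and 373. An intron of M01F1.8 on III held a region that scored 431, with its summit 1012 bp upstream of M01F1.9.

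SYD-9-GFP summits were concentrated just upstream of protein-coding genes and were scarce in coding sequence. Within 500 bp of an annotated 5' end lay 414 of 941 summits (44%, 95% interval 40.8 to 47.2), against 23.3% with shifted positions, a 1.89-fold excess. Of these, 358 lay upstream, at a median of 212 bp, and 56 downstream, at a median of 192.5 bp. Intergenic sequence held 66.4% of summits against 36.9% with shifted positions, and 5' UTRs held 2.44% against 1.38%. Coding exons held 4.46% against 25.3%, 3' UTRs 0.638% against 3.32%, and introns 26% against 33.1%. In the upper tail, the one-sided permutation p was 0.001 for 5' ends and intergenic sequence, the smallest possible, and 0.0050 for 5' UTRs. For coding exons, 3' UTRs and introns it was 0.001 in the lower tail, also the smallest possible.

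**Figure D2:**
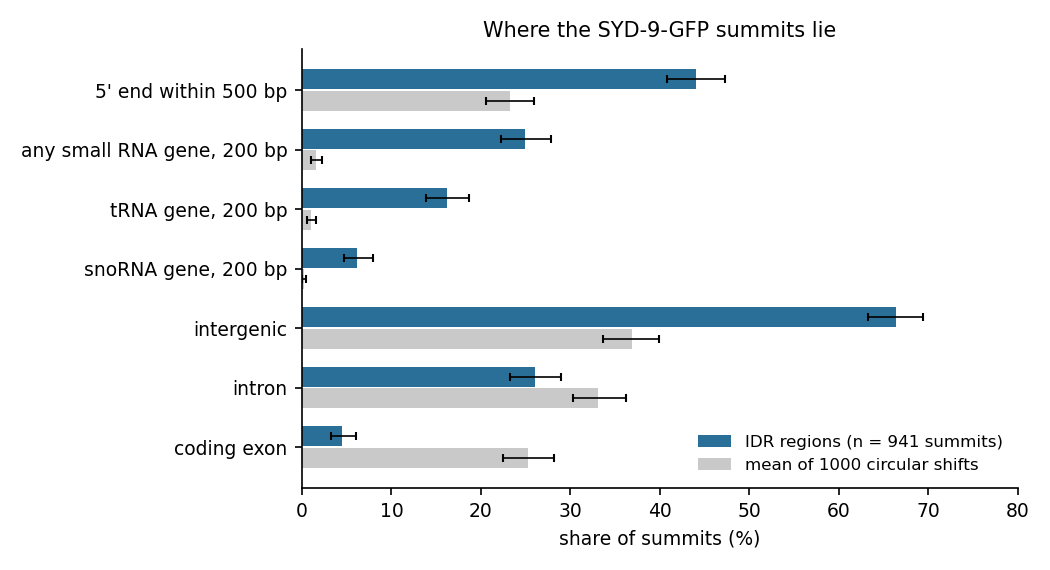
Share of the 941 summits (blue, in percent) at each kind of position, with the mean of 1000 circular shifts (grey). Error bars are exact 95% intervals for the observed shares and the central 95% of the shifts, and 25% of summits lay within 200 bp of a small RNA gene against 1.54% after shifting.

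Promoters shared by genes on opposite strands held more summits than random promoter positions did. Of the 414 summits near 5' ends, 88 (21.3%) lay within 500 bp of the 5' ends of genes on both strands, against 9.74% of random promoter positions, a 2.18-fold excess. The two-sided permutation p was 0.002, the smallest that 1000 draws can give. Most summits lay upstream, and against positions drawn at the summits' own sides and distances the excess was 1.64-fold (two-sided permutation p = 0.002, the smallest possible). The fold fell to 1.37 with a distance of 1000 bp. An example is the region between the histone genes his-67 and his-68 on I (9988900 to 9989075, score 260), whose summit lay 230 bp from the former and 139 bp from the latter. Summits near 5' ends and elsewhere had alike signal values, with medians of 130.5 and 131.1 (log2 difference -0.01, permutation test, two-sided p = 0.926).

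Summits were concentrated at genes for small non-coding RNAs, most of them tRNA and snoRNA genes. Within 200 bp of a small RNA gene lay 235 summits (25%, 95% interval 22.2 to 27.9), against 1.54% with shifted positions, a 16-fold excess. By class, 152 summits lay at tRNA genes (16-fold), 58 at snoRNA genes (34.9-fold), 15 at snRNA genes (27.7-fold) and 9 at miRNA genes (7.67-fold). The one-sided permutation p was 0.001 for each of these, the smallest possible. At rRNA genes 4 summits were found, all on mitochondrial DNA, a 1.2-fold ratio with a one-sided permutation p of 0.494 (2 summits and a ratio of 0.713 without replicate 1, one-sided permutation p = 0.826). On nuclear chromosomes alone, without the closely packed tRNA genes of mitochondrial DNA, the excess was 36.1-fold for all small RNA genes and 51.8-fold for tRNA genes. The overall fold was 9.49 with a distance of 500 bp, the snoRNA fold was 62.7 among the 470 highest-scoring regions, and the snRNA fold was 17.9 without replicate 2.

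The summits sat at different places at tRNA and snoRNA genes. Of 612 nuclear tRNA genes 150 (24.5%) had a summit within 200 bp, and over all 160 bound tRNA genes, mitochondrial ones included, the median summit lay 11 bp downstream of the gene's 5' end, with 54.4% of summits inside the gene. Of 346 snoRNA genes 58 (16.8%, 95% interval 13.0 to 21.1) were bound, and their median summit position was -51.5 bp relative to the 5' end, with 4 summits inside the gene. No tRNA isotype passed the threshold. Among the extremes, 5 of 13 tRNA-Cys and 2 of 20 tRNA-Asn genes were bound (adjusted Fisher exact p of 0.987 for both), as were 0 of 1 tRNA-Sec gene and 0 of 5 without a named isotype. Bound snRNA genes numbered 10 of 129 and included sls-2.1, sls-2.2 and sls-2.4, which encode the SL2 spliced leader RNA. They also included sup-6, sup-39 and mir-1831, which the annotation used here classes as snRNA genes, and of which the last pair shared a summit. Bound miRNA genes numbered 8 of 261 and included mir-51, mir-52 and mir-53 of a single family, with scores of 377 and 316 for mir-51 and mir-52. Of all tRNA genes 25 had surroundings, the gene itself included, that are nearly all unique in the genome. The series holds no precipitation from worms without the tag.

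Regions were over-represented on the X chromosome and under-represented on V. The X chromosome held 230 of the 923 nuclear regions (24.9%, 95% interval 22.2 to 27.8) and 13.7% of protein-coding genes, a ratio of 1.82 (two-sided exact binomial p = 1.04e-19). Against its 17.7% of the nuclear length the ratio was 1.41 (two-sided exact binomial p = 3.73e-08). X carries 276 tRNA genes, of which 72 were bound, and without the summits at small RNA genes the ratio was 1.68. Chromosome V held 13.0% of regions and 25% of genes, and III held 16.9% of regions and 13.2% of genes.

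**Figure D3:**
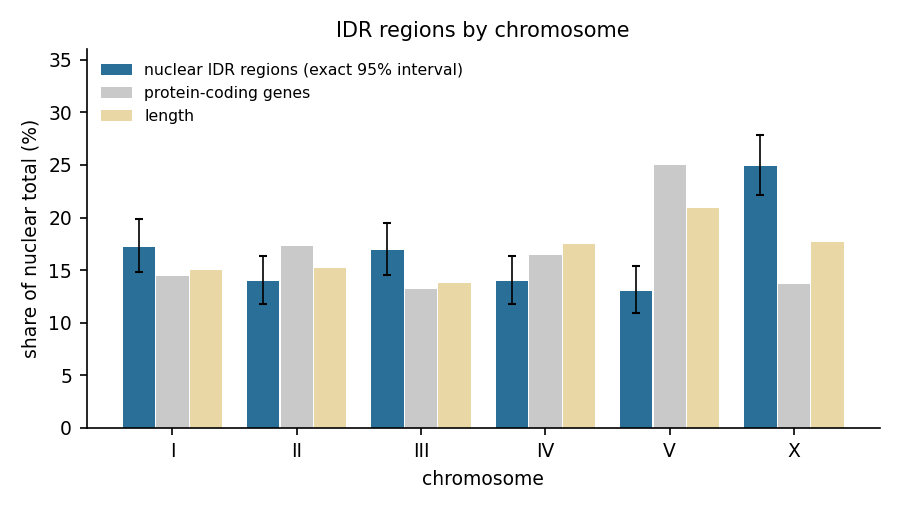
Share of the 923 nuclear IDR regions (blue, with exact 95% intervals), of protein-coding genes (grey) and of length (yellow) on each chromosome, in percent. X holds 24.9% of regions and 13.7% of genes, and V holds 13.0% of regions and 25% of genes.

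Along the autosomes, the middle 33.3% of each chromosome's length held 296 of 693 regions (42.7%, 95% interval 39.0 to 46.5) and 38.1% of genes, a ratio of 1.12 (two-sided exact binomial p = 0.0137). The ratio no longer passed the threshold without replicate 2 (ratio 1.09, exact binomial p = 0.0611), among the 470 highest-scoring regions (1.13, p = 0.0642) and without summits at small RNA genes (1.08, p = 0.168).

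Genes for protein folding, muscle structure and the ribosome stood out among the protein-coding genes with a summit. The series holds no precipitation from worms without the tag. Binding by SYD-9 at these genes therefore cannot be told apart from signal that the antibody gives without it. In all, 485 of 19973 nuclear protein-coding genes had a summit within 500 bp of a 5' end, and of the 18 lists 5 were enriched and 1 depleted by Fisher's exact test, two-sided, with adjusted p under the threshold. Among heat shock and folding genes 10 of 28 were bound (odds ratio 22.8, 95% interval 9.33 to 52.3, adjusted Fisher p = 4.55e-09). They included hsp-3, an Hsp70 of the endoplasmic reticulum, dnj-13, a J-domain protein, hsp-1, the cytosolic Hsc70, and cct-7, a chaperonin subunit, with scores of 165, 165, 156 and 155. The summit counted for dnj-19, 386 bp away, lay 10 bp from the 5' end of nhr-47 and was counted in the nuclear hormone receptor list too. Among body wall muscle genes 9 of 30 were bound (odds ratio 17.5, 95% interval 7.02 to 40.2, adjusted Fisher p = 1.12e-07). The highest scores were at unc-112, a kindlin of muscle attachments (194), unc-60, which encodes cofilins (150), unc-54, the major myosin heavy chain (133), and unc-22, twitchin (130). Among cytosolic ribosomal protein genes 15 of 80 were bound (odds ratio 9.53, 95% interval 5.01 to 17.1, adjusted Fisher p = 4.55e-09), with rpl-3 (478), rpl-35 (276), rps-24 (249) and rpl-15 (238) the highest. The count includes rsl-24D1 (102), whose RefSeq symbol is not that of a ribosomal protein gene and which matched the list through its Ensembl symbol.

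Genes of the mitochondrial respiratory chain and chromatin regulators were enriched too, and chemosensory receptor genes were depleted. Bound respiratory chain genes numbered 6 of 37 (odds ratio 7.86, 95% interval 2.67 to 19.2, adjusted Fisher p = 0.000878), among them the cytochrome oxidase genes cox-5B (163) and cox-6B (148), nuo-2 of complex I (130) and cyc-1 of complex III (123). Bound chromatin regulators numbered 6 of 40 (odds ratio 7.17, 95% interval 2.45 to 17.4, adjusted Fisher p = 0.00114), among them lin-35, the retinoblastoma homologue (242), the histone methyltransferase gene met-1 (163), mrg-1 (130) and lin-54 (109). The summit counted for lin-54, 422 bp away, lay 29 bp from the 5' end of rpl-12 and was counted in the ribosomal list too. Of chemosensory receptor genes 4 of 1311 were bound (odds ratio 0.116, 95% interval 0.0313 to 0.299, adjusted Fisher p = 4.55e-09). Against circular shifts the count was also below expectation but did not pass (observed over expected 0.672, adjusted permutation p = 0.833). Those shifts compare a list with shifted summits and not with other genes, and summits in general were 1.89-fold in excess near 5' ends. They therefore do not test depletion relative to other genes. The bound receptor genes were srh-269, sri-5, srh-16 and srh-2, with scores of 163, 139, 120 and 105, and the summit at srh-269 also lay at the tRNA gene T03E6.t1.

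The nervous system lists did not pass the threshold over all genes, though each of the pair with bound members did under some other settings and not under others. Circular shifts do not compare a list with other genes, and all summits together were 1.89-fold in excess near 5' ends over shifted ones. A pass against shifts can thus reflect that general excess and is not specific to a list. Of synaptic vesicle and active zone genes 3 of 35 were bound (odds ratio 3.78, adjusted Fisher p = 0.105): syd-2, the liprin-alpha gene (157), dnj-14 (146) and dyn-1, the dynamin gene (115), all on X. The list passed against circular shifts (observed over expected 7.25, adjusted permutation p = 0.0270), but had no bound member at 250 bp and an odds ratio of 1.85 against candidate regions (adjusted Fisher p = 0.739). Of axon guidance genes 3 of 30 were bound (odds ratio 4.49, adjusted Fisher p = 0.0800): unc-76 (109), the semaphorin gene mab-20 (97.6) and the cell adhesion gene sax-7 (95.7), the last with no region of replicate 1 within 200 bp. This list passed at 250 bp (odds ratio 7.89, adjusted Fisher p = 0.0215), at 1000 bp (4.37, adjusted Fisher p = 0.0411) and against circular shifts (observed over expected 7.58, adjusted permutation p = 0.0360), while without replicate 1 only 1 of its genes was bound (odds ratio 1.6, adjusted Fisher p = 0.774). None was bound by the 470 highest-scoring regions, and against candidate regions the odds ratio was 1.85 (adjusted Fisher p = 0.739). None of 35 neuronal transcription factors was bound, nor any of the 39 epidermal, 25 intestinal, 34 germline or 25 patterning genes tested. Core histones had 5 of 72 bound (odds ratio 3.02, adjusted Fisher p = 0.0788), counted as separate genes. Of these, his-67 and his-68 shared a summit, and his-37 scored 140. The genes his-61 and his-62 also shared a summit (95.5), which had no region of replicate 1 within 200 bp. The histone list passed without replicate 1 (odds ratio 3.49, adjusted Fisher p = 0.0466), at 250 bp (5.32, adjusted Fisher p = 0.0122), with matching by Ensembl symbol (4.47, adjusted Fisher p = 0.0188) and against circular shifts (observed over expected 13.7, adjusted permutation p = 0.0120). It did not pass without replicate 2 (odds ratio 1.67, 3 bound, adjusted Fisher p = 0.709), at 1000 bp (2.12, adjusted Fisher p = 0.199) or against candidate regions (2.86, adjusted Fisher p = 0.195). Splicing genes had 3 of 44 bound, snr-1 (152), rsp-2 (126) and prp-8, with an odds ratio of 2.95 and an adjusted Fisher p of 0.164, and passed at 1000 bp (3.65, adjusted Fisher p = 0.0411) and against circular shifts (observed over expected 8.85, adjusted permutation p = 0.0154). At 250 bp no splicing gene was bound, and against candidate regions the odds ratio was 1.05 (adjusted Fisher p = 0.956). Of 269 nuclear hormone receptors 5 were bound, led by nhr-1 (176), nhr-142 (153), nhr-40 (136) and nhr-41, with an odds ratio of 0.759 and an adjusted Fisher p of 0.956. The ratio was above 1 against candidate regions (1.15, adjusted Fisher p = 0.956) and circular shifts (observed over expected 3.38, adjusted permutation p = 0.0683), and the summit at nhr-41 lay inside the tRNA gene Y104H12A.t1. The cell cycle list had the inhibitor gene cki-1 (133) as 1 of 34, and the pharynx list had the T-box gene tbx-2 (98.8) as 1 of 17, which was not bound without replicate 2 or among the 470 highest-scoring regions. The cell cycle ratio of 1.22 (adjusted Fisher p = 0.850) fell below 1 at 250 bp, at 1000 bp and against candidate regions.

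Against genes with any pooled candidate region near a 5' end, heat shock (odds ratio 9.39), muscle (5.18) and ribosomal genes (3.33) stayed past the threshold. Respiratory chain genes (2.62, adjusted Fisher p = 0.195), chromatin regulators (2.23, p = 0.351) and chemosensory receptors (0.639, p = 0.838) did not. The respiratory chain (4.83, adjusted Fisher p = 0.180) and chromatin (4.45, p = 0.181) calls were also lost among the 470 highest-scoring regions, and the ribosomal call at 250 bp (2.76, adjusted Fisher p = 0.230).

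**Figure D4:**
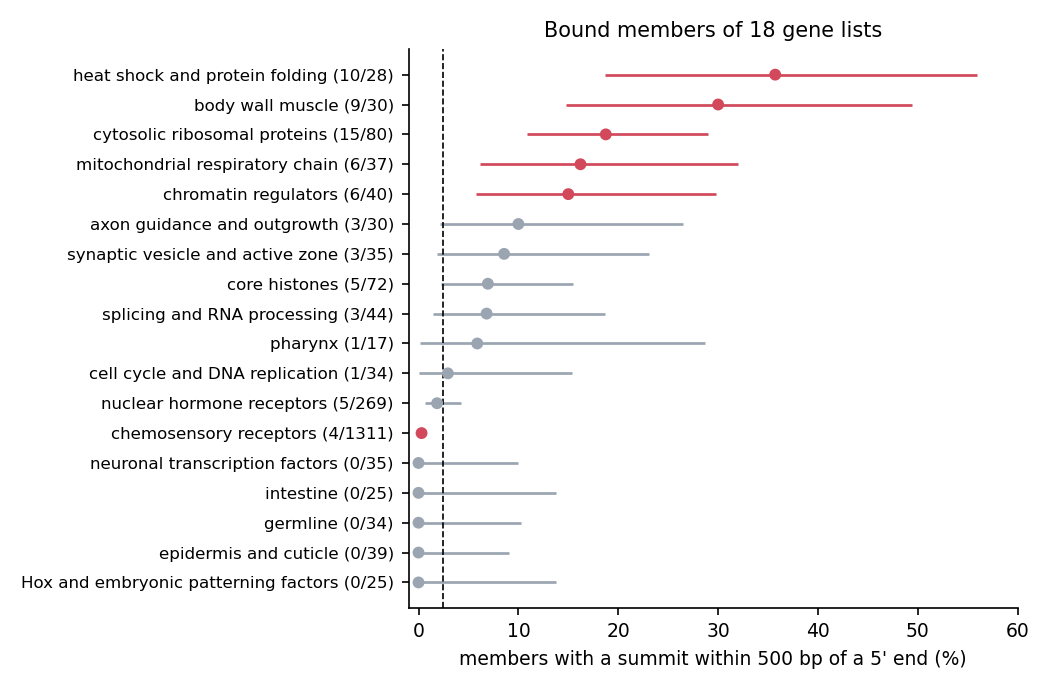
Percent of each list's members with a summit within 500 bp of a 5' end, as points with exact 95% intervals, with bound and total members in brackets and the share over all genes as a dashed line. Red lists passed the threshold, from 35.7% of heat shock and folding genes to 0.305% of chemosensory receptors.

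The words GAGAGA, ACGCAG and GCACAC occurred more often around the summits than in the flanks. The 6-mer GAGAGA (reverse complement TCTCTC) lay within 50 bp of the summit in 261 of 941 regions and in 91 flank windows (adjusted exact binomial p = 1.87e-23). ACGCAG lay in 133 summit windows and 19 flank windows (adjusted exact binomial p = 7.56e-21), and GCACAC in 144 and 28 (adjusted exact binomial p = 2.63e-20). Of 2080 6-mers 388 were enriched and 262 depleted against flanks, which had 37.5% GC against 50.9% at the summits. Against dinucleotide shuffles of the summit windows, which keep base composition, 62 were enriched and 51 depleted, and GAGAGA, ACGCAG and GCACAC stayed enriched over 125, 49 and 68 shuffled windows. The lowest p against shuffles was that of CACACA, found in 173 summit windows and 64 shuffled ones (adjusted exact binomial p = 6.64e-16). The ratio of summit to flank windows for ACGCAG was 7.0 with both replicates and 4.1 without replicate 2.

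The tagged gene itself lay among several regions. On X, syd-9 (7218097 to 7226829, plus strand) had 4 IDR regions within 20000 bp of the gene but none within 500 bp of its 5' end. The nearest, at 7215008, lay 3089 bp upstream of it (score 174), and a summit at 7224721 lay in an intron of syd-9 (141). The others, at 7232497 in the 5' UTR of F46H5.3 (172) and at 7234967 in an intron of that gene (95.3), lay beyond its 3' end. In the same window the pooled list had 21 candidate regions, a count at the 99.6 percentile of genomic windows of 48733 bp. The marker gene unc-119 on III (10902641 to 10908935) had 11 candidates within 20000 bp and no IDR region, the nearest lying 45614 bp away. That count was at the 85.0 percentile of the windows of 48733 bp, which are somewhat longer than its own.

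**Figure D5:**
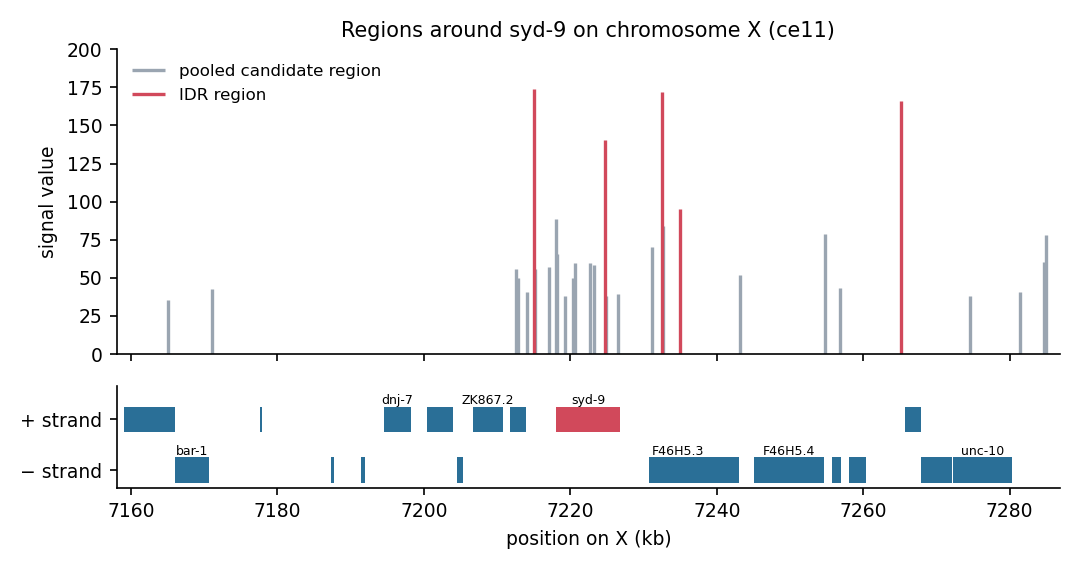
Signal value (y) of pooled candidate regions (grey) and IDR regions (red) along X around syd-9 (x, position in kb), with protein-coding genes by strand below. Within 20000 bp of syd-9 there are 21 candidate regions, of which 4 are IDR regions.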

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

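The test of covered lengths on mitochondrial DNA was chosen only after the result was seen. All 18 pooled candidate regions on mitochondrial DNA were IDR regions, and they lie outside the comparisons of nuclear chromosomes. They drew attention as a signal in a part of the data that those comparisons leave out. The strongest lay in COX1 (8928 to 9334, score 851), COX3 (837), ND5 (777) and CYTB (675). IDR regions covered 39.9% of mitochondrial DNA and 0.393% of nuclear DNA, a ratio of 102. Many copies of mitochondrial DNA in each cell may give such regions without binding, and the deposited lists hold no values of the control library, so copies and binding cannot be told apart. No biological explanation was tested.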

How the results depend on the processing

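The settings with nuclear chromosomes only, without summits at small RNA genes, with symbol matching and with matched promoter draws were chosen only after the results were seen. Of 55 planned recomputations of results that answer a comparison, 48 stayed on their side of the threshold (for counts, within 1.5 times the count; for rho, within its interval), 2 lost their call, 5 counts moved further and no called value reversed. Of 13 added ones 12 stayed and 1 lost its call. Among those that stayed, 3 planned values and 1 added value, all of the signal by position, passed no threshold and changed sign. For single lists, classes and 6-mers, 152 of 168 planned and 46 of 47 added values stayed on their side, 7 lost a call and 10 gained it. Of those that stayed, 12 planned values and 1 added value passed no threshold and changed direction.

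The excess in the middle of the autosomes ranged from 1.09 to 1.14 when a replicate was left out and lost its call without replicate 2. The call was also lost among the 470 highest-scoring regions (1.13), where fewer regions were tested, and without summits at small RNA genes (1.08), where the cause was not tested. With candidate regions as background 3 lists passed the threshold, over a smaller set of genes. Enriched 6-mers numbered 195 among the 470 highest-scoring regions, with fewer windows, and 191 with 25 bp each side, in shorter windows. They numbered 62 against shuffles, which keep the base composition, and 48 for 8-mers, which are rarer words. No fold over weaker candidates could be given for rRNA genes, since none of those regions lay there. Depth is unknown, so weak sites missed for lack of reads cannot be told from unbound sites.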

Other observations

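All tests in this part were chosen after the results they bear on were seen, except the test of GC content and the comparison of small RNA genes with weaker candidate regions.

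Several strong regions lay away from small RNA genes and outside the rule for named genes, and were chosen after their values were seen. The 14-3-3 gene ftt-2 on X had summits 582 and 781 bp upstream, with scores of 362 and 266. A region on V that scored 349 had the calmodulin gene cmd-1 as its nearest 5' end, 4782 bp away. The AAA ATPase gene cdc-48.1 on II had a summit 192 bp upstream (294), and the RFX factor gene daf-19 on II had a summit 230 bp upstream (274).

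A repeated word, GAAAAGGGG, was seen in the regions at eel-1, Y62F5A.12 and hsp-1 and then counted. It lay within 100 bp of the summit in 29 of 941 IDR regions (3.08%) and in 97 of 12286 weaker candidate regions (0.790%), an odds ratio of 4.00 (95% interval 2.53 to 6.14, Fisher's exact test, two-sided p = 1.18e-08). The regions with the word also included those upstream of rps-24, atad-3, ippk-1 and C26B2.7. Counting it in the regions where it was seen favours it, so the ratio is a description. Adjacent regions, such as the pairs at eel-1 and rps-24, were counted separately, so the p-value can be too small and the interval too narrow. The summit sequences at eel-1 and Y62F5A.12 share a longer stretch around the word, and whether reads were shared between such copies was not tested.

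The concentration of summits at small RNA genes was weighed against 3 technical explanations, and no biological one was tested. Reads shared between near-identical copies do not account for the snoRNA and miRNA genes, since those with unique surroundings had a 26.6-fold excess, with 64 summits at 523 genes (permutation test, one-sided p = 0.001, the smallest possible). Taken apart, snoRNA genes had a 38.3-fold excess with 55 summits, and miRNA genes a 9.17-fold excess with 9 summits. For tRNA and snRNA genes the question stays open: 25 tRNA genes had unique surroundings, with 1 summit and a 7.87-fold ratio (permutation test, one-sided p = 0.114), and 26 snRNA genes had them, with 0 summits where shifts put 0.0114% of summits. High GC content does not account for all of the excess, since 24.6% of nuclear summits lay there, 8.41 times the highest share (2.93%) among 1000 sets of positions matched for GC. The mean share of those sets was 1.57%, so the excess over matched positions was 15.6-fold. This was smaller than the 36.1-fold excess over shifted positions on nuclear chromosomes. The share over all 941 summits was 11.4 times that of weaker candidate regions (2.19%). Those weaker regions themselves lay at small RNA genes 3.33 times as often as shifted positions (permutation test, one-sided p = 0.001, the smallest possible). Without a precipitation from worms lacking SYD-9-GFP, a signal that anti-GFP antibodies give at highly transcribed small RNA genes cannot be told apart from SYD-9 binding.

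A tRNA-like promoter element may mark the bound snoRNA genes. The word GGTTCGANNCC, the B box bound by TFIIIC, was searched with up to 1 mismatch, within 200 bp of snoRNA genes and within 100 bp of summits. Of 54 snoRNA genes with it 25 had a summit, and of 292 without it 33 did, an odds ratio of 6.71 (95% interval 3.35 to 13.5, Fisher's exact test, two-sided p = 1.58e-08). The word lay within 100 bp of 80% of summits at nuclear tRNA genes and 41.4% of those at snoRNA genes. The tRNA share is a description only, since tRNA genes carry this element themselves. Away from small RNA genes it lay near 2.01% of IDR summits and 2.43% of weaker candidates (Fisher's exact test, two-sided p = 0.610), so no excess was detected there.

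The cluster of candidate regions at syd-9 may come from extra copies of the region in the transgene. The window held 21 candidates against a median of 6, at the 99.6 percentile. Bins of 10 kb at and beside the gene held 7, 9 and 4, and the 5 bins to their left held 0 or 1. The 5 bins to their right held 1 to 3, so the edge there was less sharp. Copy number was not measured, and binding by SYD-9 at its own gene would also give more regions.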
